A study of Mus musculus with 101 samples.

How the data were processed

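The values used are estimated counts per gene, as deposited by the authors in 2 tables, 1 per experiment, with 24475 Entrez gene IDs. They were not scaled for depth, and 2.94% of the cells were not whole numbers within a tolerance of 1e-06. The design was drawn up for raw counts, so the estimated counts were rounded to whole numbers before fitting. Per the labels' protocols, mRNA libraries were made from 500 ng RNA with a KAPA mRNA HyperPrep kit, adapters carrying unique molecular identifiers (UMIs) and 14 PCR cycles. They were sequenced on an Illumina NovaSeq with 76 cycles and paired ends. Per the submitters' processing notes the genome was mm10. The aligner, the counter and the use of the UMIs are not given in the sources used here. Symbols and places were joined by Entrez ID from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. Of the IDs 24375 had a symbol and 100 had none. Among the latter ID100861531 held 1.27 to 4.43% of the counts in the AAV table and 0.418 to 3.08% in the KO table and was kept.

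The labels call the libraries of a group biological replicates and number them. No 2 libraries of a group were copies of each other: over 383 pairs within groups an index of spread, which is 1 for counting noise, ran from 6.19 to 427. The series text gives 8 mice for WT on HFD where the labels list 7 subcutaneous libraries, and the labels were followed.

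The comparisons, the gene lists, the alternatives and the rule for named genes were set before the data were examined. Each depot of each experiment was fitted apart, with all groups of that depot in the fit, and the interactions between depots were fitted over both depots of an experiment. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.219 and 0.319 for subcutaneous and epididymal fat of the AAV experiment and 0.266 and 0.341 for the KO experiment. SEs are the absolute log2 fold change divided by the square root of F. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

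Named genes were Inhbe and Acvr1c and the up to 7 largest rises and 7 largest falls among called genes with a mean of at least 1 CPM. Up to 4 called members of each list by p (or up to 3 uncalled ones) were also named. For interactions the 5 smallest adjusted p of each sign were named, with ties not ordered by p. Values given for Mest, Slc5a7, Lipe and some other genes outside this rule were added after the results were seen. CPM is counts per 1e+06 of the library total. A gene with 0 counts in a whole group was given no fold change, except Inhbe, for which a floor of 3 counts over the group gives a lower bound. Such floors and intervals cover counting error only. A few genes are not reported.

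The 32 lists covered lipid metabolism, signalling, cell types and tissues that a fat pad can carry along, and were tested in 15 comparisons by camera with a preset correlation of 0.01, adjusted over all 474 tests. Of these 175 were called, and 177 with RLE size factors. With an inter-gene correlation estimated from the data 16 were called, all in the same direction. The lists of imprinted and of liver genes were added after the results were seen.

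Counts were simulated from the mean level and the dispersion of each gene kept, with known changes in 200 genes per comparison. Of these 67 changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. This tested the fit and the calls, not the low-count filter. Recovery at 1.5, 2 and 4-fold was 65.7, 91 and 100% for the AAV in subcutaneous fat and 44.8, 77.6 and 97% in epididymal fat. For KO on chow it was 47.8, 80.6 and 92.4% in subcutaneous and 49.3, 65.7 and 86.4% in epididymal fat, and for KO on HFD 41.8, 82.1 and 98.5% and 59.7, 82.1 and 93.9%. For HFD it was 41.8, 80.6 and 95.5% (WT subcutaneous), 38.8, 80.6 and 92.4% (KO subcutaneous), 55.2, 77.6 and 92.4% (WT epididymal) and 46.3, 77.6 and 90.9% (KO epididymal). For interactions it was 17.9, 52.2 and 90.9% (diet, subcutaneous), 19.4, 50.7 and 90.9% (diet, epididymal), 16.4, 67.2 and 89.4% (AAV between depots), 20.9, 55.2 and 84.8% (KO on chow between depots) and 29.9, 61.2 and 77.3% (KO on HFD between depots). False calls ranged from 2 to 8 genes. The simulated libraries held no structure shared between samples, such as carried-over tissue, so these rates may not hold for the real libraries.

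The main results were recomputed with RLE size factors, DESeq2, no low-count filter, the replicate number as a block, limma-voom with quality weights, a tissue score as a covariate (lymph node or epididymis list) and a fit of only the 2 groups compared. Fits that leave out libraries that stood apart or carried little lymph node or much liver transcript were chosen after seeing the data, as was a tolerance of 0.1 on correlations. Each comparison was also run on up to 100 regroupings of its libraries. Gain and loss of function were compared by the correlation of log2 fold changes over shared genes and by camera on the called genes. Permutation tests used 1e+05 resamples. No library and no gene ID was left out of the main results.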

Results

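Messenger RNA was sequenced from subcutaneous and epididymal white fat of male C57BL/6NTac mice, in 101 libraries from 2 experiments. Inhbe encodes the inhibin beta E chain, whose dimer is activin E, a liver-secreted ligand of the TGF-beta family, and Acvr1c encodes ALK7, a type I receptor of that family that fat cells express. In the gain-of-function experiment, chow-fed mice carried a liver-directed adeno-associated virus (AAV8) with either a GFP control or mouse Inhbe (mInhbe), with 10 libraries per group in each depot. In the loss-of-function experiment, wild-type (WT) mice and mice lacking Inhbe (KO) received chow or a high-fat diet (HFD). This gave 8 WT chow, 7 KO chow, 7 WT HFD and 8 KO HFD subcutaneous libraries, and 8, 7, 8 and 8 epididymal ones. Totals ran from 13 to 20.2 times 1e+06 estimated counts per library, so that a floor of 3 counts stood for 0.149 to 0.231 CPM, counts scaled to the library total. Values after a gene are log2 fold changes ± SE unless a unit is named, and levels are mean CPM ± SD.

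Inhbe (Entrez 16326, chromosome 10, 127349402 to 127351848, GRCm38.p6) was the targeted gene. It had 0 counts in all 20 libraries with the GFP vector. With the mInhbe vector it had 35 to 846 counts in the 10 subcutaneous libraries (median 148, 14.5 ± 14.9 CPM) and 4 to 232 counts in the 10 epididymal ones (median 31, 2.93 ± 4.38 CPM). Pooled over each group and set against a floor of 3 counts over the GFP group, these levels were at least 880-fold higher in subcutaneous and at least 161-fold higher in epididymal fat. The mInhbe subcutaneous libraries held less of the liver gene Alb than the GFP ones (8.73 ± 2.74 against 26.3 ± 8.12 CPM). Where the Inhbe transcript was made was not tested. Effects of the vector in fat therefore cannot be credited to ligand from the liver alone. In the KO experiment Inhbe had 5 counts in 1 WT HFD subcutaneous library, 1 count in 1 KO HFD subcutaneous library, 2 counts in 1 WT HFD epididymal library and 0 in the other libraries. WT fat itself was therefore near 0, and the adipose libraries cannot check the genotype.

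The first comparison asked how the mInhbe vector changed the subcutaneous fat transcriptome on chow. Some genes of fat-cell energy metabolism fell, and some targets of SMAD transcription factors rose. None of these gene list calls held with an estimated correlation between genes. With a lymph node score as a covariate most gene calls ended, and 503 of 3801 stayed. Of 13990 genes tested, 2204 rose and 1597 fell. Most shifts were small, and 126 of the 3801 called genes changed at least 2-fold. The largest rises after Inhbe were Adamtsl2 (Entrez 77794, 3.13 ± 0.38, adjusted p = 3.84e-05), which encodes a matrix protein that binds latent TGF-beta binding protein, Sez6l (Entrez 56747, 2.94 ± 0.27, adjusted p = 1.28e-06), the gastric lipase Lipf (2.82 ± 0.36) and the imprinted zinc finger gene Zim1 (2.73 ± 0.25). These 4 genes were higher than the GFP mean of log2(CPM + 1), the kind of mean behind all such library counts, in 10 of 10 libraries. Clca3a2 (2.72 ± 0.81) and the membrane gene Prom2 (2.47 ± 0.87) were higher in 6 of 10 each. The imprinted hydrolase gene Mest (2.10 ± 0.28) and the choline transporter gene Slc5a7 (2.29 ± 0.40) also rose. The largest falls were in the major urinary protein genes Mup7 (-3.42 ± 0.45), Mup2 (-2.85 ± 0.42), Mup9 (-2.71 ± 0.47), Mup19 (-2.47 ± 0.50) and Mup11 (-2.35 ± 0.38), near-identical paralogs whose single counts are uncertain. The P450 gene Cyp2f2 fell from 157 ± 44.9 to 27.5 ± 7.05 CPM (n = 10 and 10, -2.51 ± 0.17, adjusted p = 5.06e-09), and the fast myosin gene Myh1, the only 1 of 13 skeletal muscle genes called over all genes and alone, fell by 2.31 (list adjusted p = 0.0547). Acvr1c did not pass the test (0.18 ± 0.18, adjusted p = 0.464).

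Among lipolysis genes, which carry out or gate triglyceride breakdown, 4 of 13 fell and none rose (adjusted over the list alone, 8 fell). The members were Fabp4 (-0.52 ± 0.09), the beta-3 adrenergic receptor gene Adrb3 (-0.67 ± 0.15), the monoglyceride lipase gene Mgll (-0.66 ± 0.17) and the protein kinase A gene Prkaca (-0.56 ± 0.15). The list passed camera's test (adjusted p = 0.00269, and adjusted p = 0.327 with an estimated correlation). Of 24 oxidative phosphorylation genes 17 fell, among them Sdhb (-0.61 ± 0.09) and Ndufa9 (-0.37 ± 0.07). Adjusted over the list alone 21 fell (adjusted p = 1.74e-09, and adjusted p = 0.332 with an estimated correlation). Fatty acid oxidation had 7 of 19 members lower, the same number adjusted over the list alone, with Acaa2 at -0.71 ± 0.12 (adjusted p = 0.000918, and adjusted p = 0.624 with an estimated correlation). Lipogenesis had 4 of 20 lower, again the same adjusted over the list alone, with the lipogenic regulator Thrsp at -1.29 ± 0.18 and the desaturase Scd1 at -0.72 ± 0.15 (adjusted p = 0.0028, and adjusted p = 0.585 with an estimated correlation). Targets of PPARG, the master regulator of fat cells, had 6 of 24 lower and 1 higher, the glucose transporter gene Slc2a4 (-0.96 ± 0.21) among those lower. Adjusted over the list alone 7 were lower (adjusted p = 0.00519, and adjusted p = 0.677 with an estimated correlation).

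SMAD target genes rose in 5 of 16 cases and fell in 1, with the same counts adjusted over the list alone. Ldlrad4 (1.07 ± 0.11), Pmepa1 (0.95 ± 0.14) and Skil (0.85 ± 0.17), feedback inhibitors of TGF-beta signalling, led the list (adjusted p = 0.0315, and adjusted p = 0.207 with an estimated correlation). Proliferation genes rose in 7 of 14 cases, also adjusted over the list alone, with Top2a at 0.91 ± 0.16 (adjusted p = 0.000774, and adjusted p = 0.52 with an estimated correlation). Among adipokines, secreted fat-cell hormones, 4 of 9 fell and 1 rose, both over all genes and adjusted over the list alone. The retinol carrier gene Rbp4 lay at -0.85 ± 0.12 and the leptin gene Lep at -0.98 ± 0.23, and the list missed camera's threshold (adjusted p = 0.0557). Lymph node markers rose in 3 of 13 cases, the same adjusted over the list alone, led by the B-cell genes Cr2 (0.84 ± 0.19) and Ms4a1 (0.68 ± 0.16) (adjusted p = 0.0194, and adjusted p = 0.73 with an estimated correlation). T cell markers rose in 2 of 12 cases, also adjusted over the list alone (adjusted p = 0.0134, and adjusted p = 0.679 with an estimated correlation). Mast cell genes rose in 2 of 6 cases, Kit (0.60 ± 0.12) and Cpa3 (0.74 ± 0.15), and 3 rose adjusted over the list alone (adjusted p = 0.0411, and adjusted p = 0.439 with an estimated correlation). Single members of lists that camera did not call were also higher: the macrophage genes Mrc1 (0.67 ± 0.16) and Clec7a (0.72 ± 0.17), the neutrophil gene Cxcr2 (0.72 ± 0.26), the endothelial genes Emcn (0.33 ± 0.09) and Tek (0.30 ± 0.09), and the thermogenic gene Ucp1 (1.70 ± 0.50, adjusted p = 0.0176). The mean log2 CPM of the lymph node list was 6.39 ± 0.26 with mInhbe and 6.1 ± 0.262 with GFP (difference 0.293, 2-sided permutation p = 0.0227 over 1e+05 resamples).

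With this lymph node score as a covariate 524 genes were called, of which 503 were also called without it. The fold changes of the genes called without the score were then 0.701 times as large at the median (quartiles 0.562 and 0.84) with SEs 1.06 times as large, and the calls of Adrb3, Mgll, Prkaca, Slc2a4, Scd1, Lep, Myh1, Clca3a2, Prom2, Mrc1, Clec7a, Cxcr2, Emcn, Tek and Ucp1 ended. Without GFP subcutaneous library 2 the calls of Prom2 (2.35, adjusted p = 0.0713) and Cxcr2 (0.67, adjusted p = 0.0714) also ended.

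In epididymal fat fewer genes were called for the same vector. The 2 counts do not measure how widely the vector acted in each depot. The common biological coefficient of variation was 0.319 here and 0.219 in subcutaneous fat. With the lymph node score as a covariate the subcutaneous count was 524. Of 14850 epididymal genes, 113 rose and 60 fell, and 51 changed at least 2-fold. Slc5a7 (Entrez 63993) rose from 1.54 ± 0.843 to 19.8 ± 6.42 CPM (n = 10 and 10, 3.67 ± 0.30, adjusted p = 1.55e-07) and Mest (Entrez 17294) from 193 ± 95 to 1010 ± 178 CPM (2.38 ± 0.24, adjusted p = 2.25e-06). The other large rises were Lipf (3.92 ± 0.39), the serine protease inhibitor genes Serpina3b (3.31 ± 0.30) and Serpina3a (3.17 ± 0.54), Adamtsl2 (3.27 ± 0.20), Bpifb6 (3.11 ± 0.36) and Sez6l (2.54 ± 0.20), each higher in 10 of 10 libraries. Serpina3 genes are close paralogs. The largest falls were Cyp2f2 (-2.72 ± 0.29), Lrtm1 (-2.03 ± 0.23), Cdsn (-1.46 ± 0.24), Pon1 (-1.34 ± 0.33), Pnldc1 (-1.33 ± 0.22), Grb14 (-1.22 ± 0.15), an adaptor that inhibits insulin receptor signalling, and Ces1f (-1.21 ± 0.19). Acvr1c was at -0.80 ± 0.24 and did not pass the test (adjusted p = 0.144).

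SMAD target genes rose as a list in epididymal fat, with 2 of 16 called, Pmepa1 (1.43 ± 0.22) and Nedd9 (0.81 ± 0.15), and 5 adjusted over the list alone. This call held with an estimated correlation (adjusted p = 5.39e-07 preset and 0.00617 estimated). Lipolysis had 1 of 13 members lower, Adrb3 (-0.73 ± 0.17), and 3 adjusted over the list alone (adjusted p = 0.000169, and adjusted p = 0.332 with an estimated correlation). Extracellular matrix genes rose in 3 of 25 cases and in 7 adjusted over the list alone, with the proteoglycan gene Bgn at 0.70 ± 0.11 and Tnc at 0.79 ± 0.15 (adjusted p = 6.45e-09, and adjusted p = 0.262 with an estimated correlation). Proliferation genes rose in 2 of 14 cases and in 8 adjusted over the list alone, with Tpx2 at 0.59 ± 0.13 (adjusted p = 1.62e-10, and adjusted p = 0.133 with an estimated correlation). Among inflammatory cytokines none of 10 was called over all genes and 6 rose adjusted over the list alone (adjusted p = 3.75e-05, and adjusted p = 0.284 with an estimated correlation). The smallest p belonged to the acute-phase gene Saa3 (2.31 ± 0.61, adjusted p = 0.076). Lipogenesis had Thrsp (-0.92 ± 0.17) and Scd1 (-0.88 ± 0.17) lower, with 3 of 20 adjusted over the list alone, and missed camera's threshold (adjusted p = 0.0525). Cholesterol synthesis had Insig1 (0.65 ± 0.15) and Hmgcs1 (0.67 ± 0.16) higher among 18, and 3 adjusted over the list alone (adjusted p = 2.01e-05, and adjusted p = 0.284 with an estimated correlation).

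The epididymal call count was 314 with DESeq2, 338 with limma-voom and 262 with the epididymis score as a covariate. It was lower than in the main fit with the replicate number as a block. GFP epididymal library 7 held 0.979 CPM of the epididymis gene Crisp1, against 2980 to 7040 CPM in the other GFP libraries, and library 8 held 758 CPM of the brown-fat gene Ucp1. Without both, Pon1 (-1.21, adjusted p = 0.13) and Adrb3 (-0.60, adjusted p = 0.0583) were no longer called and Serpina3a lay at 4.52.

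The vector's effect differed between depots, epididymal minus subcutaneous, for 2081 of 15416 genes, more positive in 631 and more negative in 1450. Ctnnbip1 (0.76 ± 0.14), an inhibitor of beta-catenin, had the smallest adjusted p among positive differences. Among negative ones the smallest belonged to Dennd2d (-1.32 ± 0.21), Tlcd4 (-2.49 ± 0.42), the leukocyte gene Ptprc (-1.41 ± 0.26) and Bhlhb9. Tmed4, Mpi, Pecr and Prdx6 (positive) and Osbpl9 (negative) had an adjusted p of 0.013. Other genes, among them Klf14 and Lep, shared this value, so these genes are not ranked. Acvr1c differed by -0.99 ± 0.30 (adjusted p = 0.0278). Lymph node markers had 4 of 13 members with a more negative epididymal effect, and 11 adjusted over the list alone (adjusted p = 0.00912, and adjusted p = 0.73 with an estimated correlation). Oxidative phosphorylation genes had 1 of 24 more positive, the same adjusted over the list alone (adjusted p = 0.000426, and adjusted p = 0.699 with an estimated correlation). Without GFP subcutaneous library 2 and GFP epididymal libraries 7 and 8, 877 genes were called, and with the replicate number as a block 4 were.

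The next comparison asked what loss of Inhbe did to subcutaneous fat on chow. Few genes changed, and most of those that fell were genes that the mInhbe vector had raised. Of 14220 genes, 19 rose and 17 fell. Mest fell from 36.3 ± 16.7 (8 libraries) to 2.67 ± 0.74 CPM (7 libraries; -3.75 ± 0.36, adjusted p = 1.69e-07) and was lower in 7 of 7 KO libraries. Slc5a7 (-3.90 ± 0.69, adjusted p = 0.00406), Sez6l (-3.50 ± 0.57), the pantetheinase gene Vnn1 (-2.48 ± 0.28), Zim1 (-2.39 ± 0.52), the imprinted zinc finger gene Peg3 (Entrez 18616, -2.37 ± 0.38) and Kcne1l (-1.96 ± 0.32) were the other largest falls. The largest rises were Tfr2 (1.18 ± 0.24), Arhgef37 (1.15 ± 0.25), Pnldc1 (1.11 ± 0.23), Lrtm1 (1.08 ± 0.21), the pore-forming gasdermin gene Gsdme (1.02 ± 0.17), the acute-phase gene Orm1 (0.99 ± 0.17) and the cysteine synthesis gene Cth (0.99 ± 0.17). Acvr1c was at 286 ± 36.6 CPM against 243 ± 105 (0.25 ± 0.22, adjusted p = 1).

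SMAD target genes were lower as a list, with Pmepa1 called (Entrez 65112, -1.76 ± 0.23, adjusted p = 4.66e-05) and 2 of 16 adjusted over the list alone. The list's call held with an estimated correlation (adjusted p = 0.000114 preset and 0.0257 estimated). Rbp4 (0.75 ± 0.15) was the 1 called adipokine, also adjusted over the list alone (list adjusted p = 0.26). No member of the lipogenesis, oxidative phosphorylation, lipolysis, macrophage or inflammatory cytokine lists was called over all genes. Adjusted over the list alone, 3 of 21 lipogenesis genes were higher, with Fasn at 1.18 ± 0.31 (adjusted p = 0.119; list adjusted p = 1.44e-08, and adjusted p = 0.253 with an estimated correlation). Likewise 7 of 12 inflammatory cytokine genes were lower (adjusted p = 1.16e-05, and adjusted p = 0.255 with an estimated correlation) and 2 of 15 macrophage genes were lower (adjusted p = 5.39e-07, and adjusted p = 0.362 with an estimated correlation). For oxidative phosphorylation (adjusted p = 9.34e-09, and adjusted p = 0.476 with an estimated correlation) and lipolysis (adjusted p = 0.00345, and adjusted p = 0.52 with an estimated correlation) no member was called alone. DESeq2 called 119 genes, limma-voom 272, a fit with the lymph node score 71 and a fit of only the 2 groups 23. Without WT chow library 1 and WT HFD libraries 1, 2 and 4, which carried little lymph node transcript, 102 genes were called, and 64 were called without WT HFD library 6 and KO HFD library 2, which held 165 and 375 CPM of Alb.

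**Figure D1:**
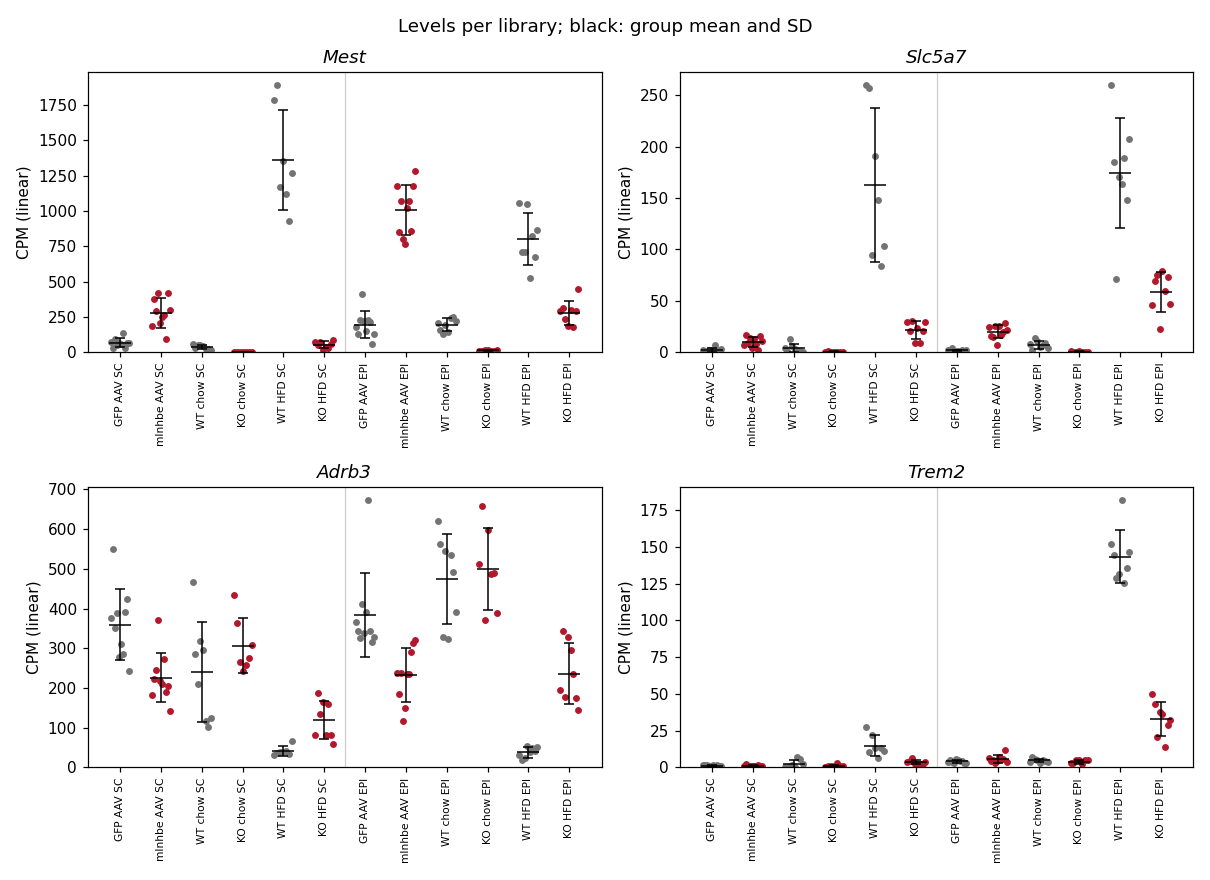
CPM of Mest, Slc5a7, Adrb3 and Trem2 per library, on linear axes that start at 0, with subcutaneous groups left and epididymal groups right of the grey line; red points are mInhbe AAV or KO libraries, grey points GFP AAV or WT libraries, and black bars the group mean and SD. Mest lay at 11.5 ± 2.83 CPM in KO chow and 192 ± 46 in WT chow epididymal fat, and Trem2 at 32.7 ± 11.7 in KO HFD and 143 ± 18 in WT HFD epididymal fat.

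In epididymal fat on chow, loss of Inhbe again lowered Slc5a7, Mest, Peg3 and Pmepa1, and raised some thermogenic genes. Of 15042 genes, 26 rose and 73 fell. Slc5a7 fell from 7.31 ± 3.88 (8 libraries) to 0.314 ± 0.282 CPM (7 libraries; -4.49 ± 0.49, adjusted p = 9.59e-07). Large falls were also seen in Mest (-4.09 ± 0.22, adjusted p = 6.62e-14), Klf14 (Entrez 619665, -2.74 ± 0.41), Peg3 (-2.20 ± 0.33), Pmepa1 (-2.09 ± 0.14, adjusted p = 5.38e-12) and Emp1 (-2.05 ± 0.18). These genes were lower in 7 of 7 KO libraries. Klf14 is an imprinted transcription factor gene close to Mest on chromosome 6 (30956021 and 30733506, GRCm38.p6). Lrtm1 (2.18 ± 0.14, adjusted p = 5.38e-12), the thyroid hormone deiodinase gene Dio2 (2.04 ± 0.29) and the glycogen synthase gene Gys2 (1.53 ± 0.27) rose in 7 of 7. The epididymis ribonuclease gene Rnase10 (5.50 ± 1.34, adjusted p = 0.0461), Col6a4 (3.46 ± 0.81), Klrb1c (3.08 ± 0.72) and Shc4 (2.25 ± 0.54) were called higher, with Rnase10 above the WT mean in 2 of 7 libraries. Acvr1c was at 0.07 ± 0.26 (adjusted p = 1).

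Thermogenic genes, which burn fuel for heat in brown and beige fat, rose in 3 of 13 cases, Dio2, Cidea (1.30 ± 0.26) and Cox8b (1.12 ± 0.26). Adjusted over the list alone 5 rose, with adjusted p = 1.91e-08 preset and 0.00707 estimated. SMAD target genes fell in 2 of 16 cases, Pmepa1 among them, and in 4 adjusted over the list alone, and this call also held (adjusted p = 6.8e-10 preset and 0.00407 estimated). Among lipogenesis genes Fasn was called (1.39 ± 0.27), and 12 of 21 were higher adjusted over the list alone (adjusted p = 1.1e-13, and adjusted p = 0.133 with an estimated correlation). The activin receptor gene Acvr1b fell (-0.55 ± 0.09) and was the 1 called member of the activin pathway list, also adjusted over the list alone (list adjusted p = 0.396). Of the lipolysis genes none was called over all genes or alone, and the smallest p was Prkaca's (0.27 ± 0.12, adjusted p = 0.729; list adjusted p = 0.137). In the epididymis list Rnase10 was the 1 of 6 called, also adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.546 with an estimated correlation), and Crisp1 ran from 0.413 to 3880 CPM over the WT chow libraries and from 3.59 to 3440 CPM over the KO chow ones.

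DESeq2 called 182 genes, limma-voom 257, a fit of only the 2 groups 162 and a fit without KO HFD library 4, which stood farthest from its group, 188. Without WT HFD libraries 4 and 5 and KO HFD library 8, which share the fit, Rnase10 (5.50, adjusted p = 0.0833), Col6a4 (3.46, 0.0591), Klrb1c (3.08, 0.0592) and Shc4 (2.24, 0.0565) were no longer called, and with the epididymis score as a covariate they lay at 1.01, 0.71, 0.58 and 1.00 (adjusted p = 1, 1, 1 and 0.739). Between depots the KO effect on chow differed for 0 of 15480 genes in edgeR's quasi-likelihood test, with 311 at an unadjusted p under 0.05, while DESeq2 called 19.

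Set against each other on chow, gain and loss of Inhbe gave most genes called for the vector opposite signs. In subcutaneous fat the genes that the vector raised hardly moved in KO as a set. Of the genes called for the mInhbe vector and tested in both experiments, 152 of 172 (88.4%) had the opposite sign in KO epididymal fat and 2699 of 3791 (71.2%) in KO subcutaneous fat. Across those genes the correlation of log2 fold changes was -0.787 and -0.633. Across all genes it was 0.037 over 14600 epididymal and -0.412 over 13875 subcutaneous genes, where genes are not independent replicates. In epididymal fat 26 genes rose with the vector and fell in KO, where independent lists would share 0.537, and 4 fell with the vector and rose in KO (0.103 for independent lists), Lrtm1, Grb14, Cdkn2c and Slc25a10. None changed the same way. In subcutaneous fat these counts were 12 (2.69), including Mest, Peg3, Zim1, Sez6l, Slc5a7, Vnn1 and Pmepa1, and 15 (2.07), including Rbp4, Cth, Orm1 and Tfr2; 1 gene, Tmem45b, fell in both. As sets, the genes raised by the vector in epididymal fat were lower in KO on chow (camera p = 2.39e-06 with an estimated correlation) and the genes lowered were higher (p = 0.000715 with an estimated correlation). In subcutaneous fat the lowered genes were higher (median 0.138, camera p = 0.0273 with an estimated correlation). The raised genes had a median of -0.025 and did not pass with an estimated correlation (camera p = 0.718, against 0.0213 preset). On HFD the shared opposite calls in epididymal fat were 61 (22.2 for independent lists) and 52 (10.4). In subcutaneous fat they were 96 (253) and 295 (117), and the correlation over all genes was -0.002. The opposite sign was found there for 1499 of the 3791 genes called for the vector (39.5%), and in epididymal fat for 144 of 172 (83.7%). Genes that the vector raised in subcutaneous fat were higher, not lower, in KO on HFD (median 0.193, camera p = 1.99e-07 preset and 0.417 estimated).

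**Figure D2:**
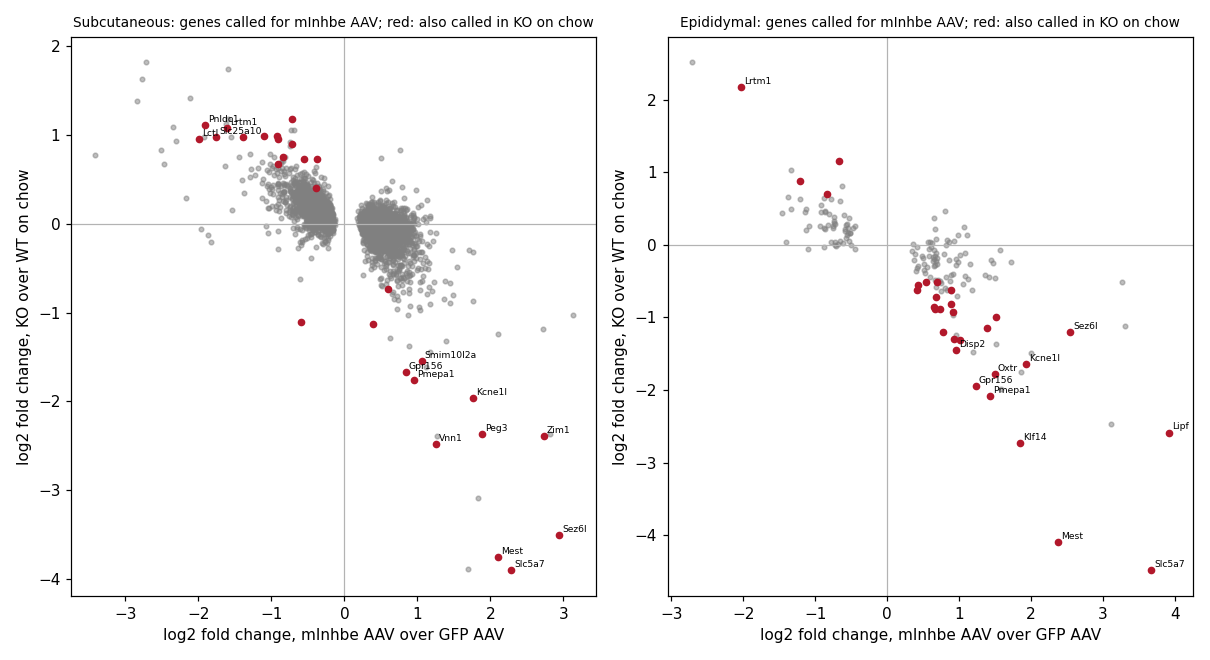
Log2 fold change with mInhbe AAV (x axis) against log2 fold change in KO on chow (y axis) for genes called for mInhbe AAV, subcutaneous left and epididymal right; each point is a gene, and red points were also called in KO. The 26 and 4 red epididymal genes all lie in the quadrants of opposite sign, and 1 of the 28 red subcutaneous genes does not.

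**Figure D3:**
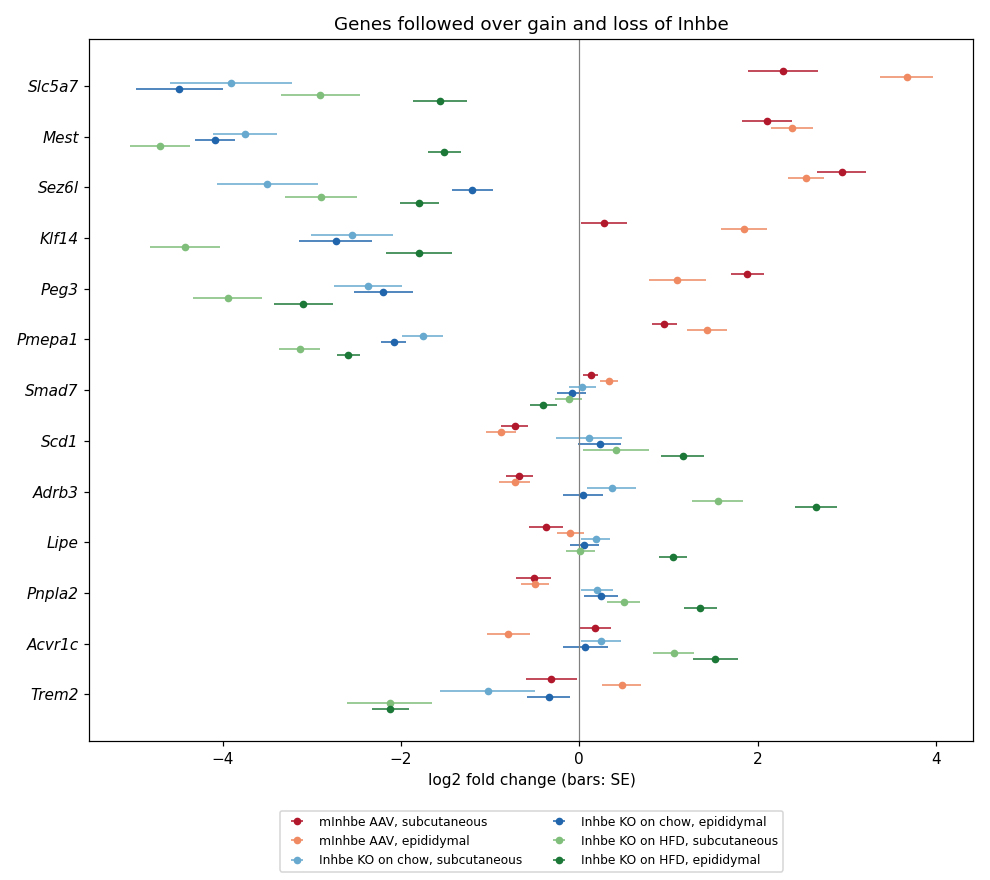
Log2 fold changes (points) and their SEs (bars) of 13 genes in 6 comparisons, with 0 marked by the grey line. Slc5a7 lay at 3.67 with mInhbe AAV and at -4.49 in KO on chow in epididymal fat, and Adrb3 at -0.73 with mInhbe AAV and 2.65 in KO on HFD.

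On HFD the question was how Inhbe loss changed fat of overfed mice. In subcutaneous fat, many matrix, lipid-associated macrophage and SMAD target transcripts fell and many fatty acid oxidation genes rose. Of these lists only the SMAD targets held with an estimated correlation. Of 14220 genes, 1041 rose and 1647 fell. The ethanol-inducible P450 gene Cyp2e1 rose from 251 ± 174 (7 libraries) to 2780 ± 659 CPM (8 libraries; 3.48 ± 0.34, adjusted p = 7.9e-09), followed by Dio2 (3.40 ± 0.45), Cyp2f2 (3.36 ± 0.28), the imprinted gene Nap1l5 (2.89 ± 0.24), Pon1 (2.76 ± 0.43), and the Mup paralogs Mup18 (4.68 ± 1.33) and Mup9 (2.62 ± 0.68). Mest fell from 1360 ± 354 to 51.3 ± 23.5 CPM (-4.71 ± 0.34, adjusted p = 2.45e-11). Tmem132b (-6.12 ± 0.48), Gsg1l (-5.86 ± 0.52), the orphan receptor gene Gpr50 (-5.70 ± 0.54), Saa3 (-5.17 ± 0.68), Pramel13 (-5.08 ± 0.41) and Lipf (-4.53 ± 0.31) fell as well. All 14 changed in 8 of 8 KO libraries. Acvr1c rose from 163 ± 60.5 to 336 ± 42.7 CPM (1.06 ± 0.23, adjusted p = 0.00136).

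SMAD target genes fell in 10 of 16 cases, also adjusted over the list alone, Pmepa1 (-3.14 ± 0.23) and Nedd9 (-1.18 ± 0.20) among them, with adjusted p = 9.51e-06 preset and 0.0102 estimated. Extracellular matrix genes fell in 15 of 25 cases and 20 adjusted over the list alone, with Bgn at -0.68 ± 0.10 and the collagen gene Col5a2 at -1.06 ± 0.19 (adjusted p = 1.59e-08, and adjusted p = 0.327 with an estimated correlation). Markers of lipid-associated macrophages, which gather around dying fat cells, fell in 9 of 12 cases and 10 alone, with Gpnmb at -2.07 ± 0.39 and Trem2 at -2.13 ± 0.48 (adjusted p = 1.06e-05, and adjusted p = 0.295 with an estimated correlation). Endothelial genes fell in 7 of 10 cases, 8 adjusted over the list alone, with Tie1 at -0.89 ± 0.14 (adjusted p = 1.06e-05, and adjusted p = 0.168 with an estimated correlation). Fatty acid oxidation genes rose in 10 of 19 cases, 12 adjusted over the list alone, with the lipid-sensing receptor gene Ppara at 1.17 ± 0.17 (adjusted p = 9e-06, and adjusted p = 0.468 with an estimated correlation). Lipolysis genes rose in 2 of 13 cases, Adrb3 (1.55 ± 0.29) and Abhd5 (0.54 ± 0.17), with 3 alone, and the list missed camera's threshold (adjusted p = 0.0781). Lymph node markers had none of 13 called over all genes or alone and were higher as a list (adjusted p = 0.00456, and adjusted p = 0.73 with an estimated correlation), and 3 of the 7 WT HFD libraries carried little lymph node transcript.

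The subcutaneous count was 5552 with limma-voom, where Mup18 was not called (adjusted p = 0.158), and without WT HFD library 6 and KO HFD library 2 Abhd5 was no longer called (0.42, adjusted p = 0.0953) and Mup9 lay at 3.36. Without WT chow library 1 and WT HFD libraries 1, 2 and 4, Tmem132b lay at -5.44, Gpr50 at -5.05, Saa3 at -4.44 and Mup18 at 5.37, all still called.

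In epididymal fat on HFD, loss of Inhbe raised most genes of lipolysis, lipogenesis and oxidation and lowered most macrophage, matrix and proliferation genes. Of these lists only the lipid-associated macrophage one held with an estimated correlation. Bulk libraries cannot tell whether the metabolic rises reflect more transcript per fat cell or a larger share of fat cells. Of 15042 genes, 2559 rose and 3031 fell. Cyp2e1 rose from 158 ± 159 to 3840 ± 1500 CPM (8 libraries each; 4.62 ± 0.48, adjusted p = 8.01e-09). The lipid droplet gene Cidea rose from 1.79 ± 0.596 to 15.6 ± 7.23 CPM (3.14 ± 0.27) and Thrsp from 118 ± 44 to 987 ± 381 CPM (3.08 ± 0.24). Mrgprg (5.55 ± 0.82), Asb12 (3.70 ± 0.44), Slc9a2 (3.40 ± 0.59) and Nap1l5 (3.37 ± 0.28) rose as well. Gpr50 fell from 62.6 ± 19.5 to 1.29 ± 0.956 CPM (-5.57 ± 0.41, adjusted p = 2.31e-11). The other 6 largest falls were the liver genes Bhmt (-5.98 ± 1.43), Serpina1b (-5.47 ± 1.20), Fga (-5.21 ± 1.44), Uox (-5.19 ± 1.31), Hpx (-5.13 ± 0.73) and Gnmt (-5.10 ± 1.11). WT HFD libraries 4 and 5 held 798.1 and 3261 CPM of the liver gene Alb and KO HFD library 8 held 46.4, against 0.843 to 1.37 in the other WT and 14.9 to 21.8 CPM in the other KO libraries. Without these 3, Bhmt (-0.35, adjusted p = 0.858), Fga (-0.31, adjusted p = 0.896) and Uox (-0.23, adjusted p = 0.9) were no longer called and Serpina1b turned (0.29, adjusted p = 0.676), while Hpx lay at -3.60 and Cyp2e1 at 5.46. Acvr1c rose from 89.6 ± 29.2 to 257 ± 93.6 CPM (1.53 ± 0.25, adjusted p = 1.5e-05).

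Lipolysis genes rose in 11 of 13 cases, also adjusted over the list alone: Adrb3 (2.65 ± 0.24), the triglyceride lipase gene Pnpla2 (1.36 ± 0.18), its activator Abhd5 (0.87 ± 0.12) and the hormone-sensitive lipase gene Lipe (Entrez 16890, 1.05 ± 0.16) among them (adjusted p = 6.07e-07, and adjusted p = 0.232 with an estimated correlation). Lipogenesis genes rose in 18 of 21 cases, 19 adjusted over the list alone, where 1 fell, with Acaca at 2.11 ± 0.21 and Fasn at 2.40 ± 0.27 (adjusted p = 4.69e-13, and adjusted p = 0.168 with an estimated correlation). All 24 oxidative phosphorylation genes rose, also adjusted over the list alone, with Ndufs1 at 0.90 ± 0.09 (adjusted p = 4.48e-18, and adjusted p = 0.255 with an estimated correlation). Fatty acid oxidation genes rose in 17 of 19 cases and 1 fell, the same alone, with Cpt2 at 1.26 ± 0.14 (adjusted p = 3.21e-11, and adjusted p = 0.232 with an estimated correlation). PPARG targets rose in 17 of 24 with 1 lower, the same alone, with Slc2a4 at 2.44 ± 0.16 (adjusted p = 2.27e-09, and adjusted p = 0.262 with an estimated correlation). Antilipolytic genes, which restrain triglyceride breakdown, rose in 7 of 11 cases and fell in 1, the same alone, with the lactate receptor gene Hcar1 at 1.57 ± 0.22 and the lipase inhibitor Hilpda at -1.32 ± 0.17 (adjusted p = 0.0315, and adjusted p = 0.284 with an estimated correlation).

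Lipid-associated macrophage genes fell in 10 of 12 cases, also adjusted over the list alone, with Ctsk at -2.05 ± 0.14, Cd9 at -1.48 ± 0.10 and Trem2 (Entrez 83433) at -2.12 ± 0.21, and adjusted p = 1.1e-13 preset and 0.0102 estimated. General macrophage genes fell in 13 of 15 cases, with Cd68 at -1.72 ± 0.20; adjusted over the list alone 14 fell and 1 rose (adjusted p = 1.46e-10, and adjusted p = 0.232 with an estimated correlation). Mast cell genes fell in 6 of 8 cases, also alone, with Cpa3 at -1.81 ± 0.23 (adjusted p = 0.000185, and adjusted p = 0.284 with an estimated correlation). Inflammatory cytokine genes fell in 9 of 15, also alone, with Ccl2 at -1.81 ± 0.27 (adjusted p = 0.00277, and adjusted p = 0.337 with an estimated correlation). Extracellular matrix genes fell in 16 of 25 cases, also alone, with Timp1 at -1.97 ± 0.23 (adjusted p = 1.64e-06, and adjusted p = 0.39 with an estimated correlation). All 14 proliferation genes fell, also alone, with Ccna2 at -1.53 ± 0.13 (adjusted p = 2.15e-10, and adjusted p = 0.133 with an estimated correlation). SMAD target genes fell in 9 of 16 cases and rose in 1, the same alone, with Pmepa1 at -2.59 ± 0.13 (adjusted p = 0.000159 preset and 0.048 estimated). Neutrophil genes fell in 2 of 5 cases, also alone, with S100a8 at -1.28 ± 0.24 (list adjusted p = 0.518).

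**Figure D4:**
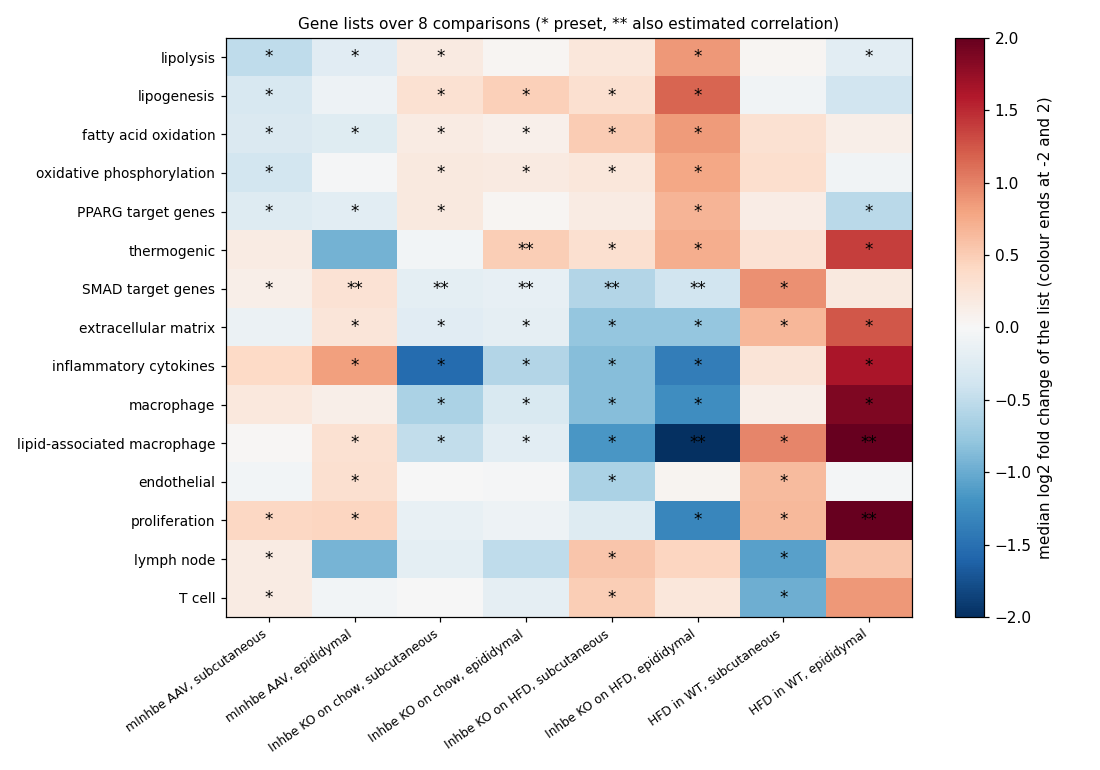
Median log2 fold change (colour) of 15 gene lists (vertical) in 8 comparisons (horizontal); 1 star marks a list called by camera with the preset correlation and 2 stars a list also called with an estimated one. SMAD target genes had 2 stars in 5 of the 8 comparisons, and lipid-associated macrophage genes lay at -2.09 in KO on HFD and 4.41 with HFD in WT in epididymal fat.

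On HFD the KO effect differed between depots for 2264 of 15480 genes, more positive in epididymal fat for 1201 and more negative for 1063. Mest (3.19 ± 0.36) and the adipokine gene Retn (2.05 ± 0.23) led the positive differences with Krt79, Rhbdl1 and Vnn3, and Nfya (-0.99 ± 0.12), Skap2, Pacc1, Dlg3 and Taok3 the negative ones. Lipogenesis genes had 13 of 21 members with a more positive epididymal effect and 14 alone (adjusted p = 2.09e-06, and adjusted p = 0.326 with an estimated correlation). Lipolysis genes had 8 of 13, with 8 positive and 1 negative alone (adjusted p = 0.000268, and adjusted p = 0.337 with an estimated correlation), and endothelial genes had 7 of 10, and 8 alone (adjusted p = 1.96e-06, and adjusted p = 0.193 with an estimated correlation). Adipokines had 6 of 10, the same adjusted over the list alone, and held with an estimated correlation (adjusted p = 2.98e-07 preset and 0.0393 estimated).

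The KO effect also differed between diets. In subcutaneous fat 304 of 14220 genes had a different KO effect on HFD than on chow, 55 more positive and 249 more negative, with Cyp2e1 (3.15 ± 0.44), Cyp2f2, Elovl7, Nap1l5 and Ppp1r3b leading the positive and the haptoglobin gene Hp (-2.19 ± 0.23), Ubd, Fam83d, Ctsl and Lrg1 the negative differences. In epididymal fat 2487 of 15042 genes differed, 1178 more positive and 1309 more negative. Disp2 (2.48 ± 0.24), the lipase gene Ces1d (2.17 ± 0.23), Car1, Mest (2.57 ± 0.27) and Aldh5a1 led the positive and Cd9 (-1.49 ± 0.14), Ctsk (-1.81 ± 0.19), C2cd2, Stxbp2 and Gla the negative differences. Lipolysis genes had 9 of 13 members with a more positive KO effect on HFD and 11 alone (adjusted p = 7.73e-07, and adjusted p = 0.232 with an estimated correlation). Lipid-associated macrophage genes had 10 of 12 with a more negative one, also alone (adjusted p = 6.57e-14 preset and 0.0102 estimated). Acvr1c differed in epididymal fat (1.46 ± 0.36, adjusted p = 0.00464) and did not pass in subcutaneous fat (0.81 ± 0.32, adjusted p = 0.206). The subcutaneous count was 569 with DESeq2 and 2500 with limma-voom, and the epididymal count was 3945 with limma-voom.

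HFD itself reshaped both depots of WT mice. In subcutaneous fat 3213 genes rose and 3063 fell. The largest rises were Gpr50 (7.63 ± 0.64), the integrin gene Itgad (7.20 ± 0.43), Lipf (6.93 ± 0.37), the tryptophan hydroxylase gene Tph2 (6.88 ± 0.39), Cacng5 (6.31 ± 0.56), Tmem132b (6.12 ± 0.47) and Aadac, which lay at 3.46 ± 2.08 CPM on HFD with 0 counts in all 8 chow libraries. Cyp2f2 fell from 226 ± 41.2 to 3.76 ± 1.73 CPM (-5.88 ± 0.31), followed by Slfn4 (-5.59 ± 1.10), Clca3a2 (-5.41 ± 1.28), Mup18 (-4.62 ± 1.32), Cyp1a1 (-4.39 ± 0.53) and Pon1 (-4.35 ± 0.44), and Mup10 was at 0 CPM on HFD against 3.05 ± 7.74 on chow. Acvr1c fell (-0.57 ± 0.23, adjusted p = 0.0428). Cholesterol synthesis genes rose in 15 of 18 cases, with Lss at 1.59 ± 0.14; adjusted over the list alone 15 rose and 1 fell, and the call held (adjusted p = 1.45e-10 preset and 0.0295 estimated). Extracellular matrix genes rose in 15 of 25, also alone, with Sparc at 1.39 ± 0.15 (adjusted p = 1.38e-05, and adjusted p = 0.476 with an estimated correlation). SMAD targets rose in 9 of 16 with 1 lower, also alone (adjusted p = 0.00468, and adjusted p = 0.172 with an estimated correlation). All 6 Schwann cell genes fell, also alone (adjusted p = 8.08e-05, and adjusted p = 0.232 with an estimated correlation), as did all 3 mesothelium genes (adjusted p = 0.0335, and adjusted p = 0.232 with an estimated correlation). Lymph node markers had no called member over all genes or alone and were lower as a list (adjusted p = 0.0396, and adjusted p = 0.839 with an estimated correlation), and WT HFD libraries 1, 2 and 4 carried little lymph node transcript. The count was 3867 when only the 2 groups were fitted. Without WT HFD library 6 and KO HFD library 2 Acvr1c was no longer called (-0.40, adjusted p = 0.0651). Without WT chow library 1 and WT HFD libraries 1, 2 and 4 Mup10 was not (adjusted p = 0.09), Slfn4 lay at -6.39, Clca3a2 at -4.11, Itgad at 6.56, Tmem132b at 5.42 and Mup18 at -5.47, and with limma-voom Mup18 turned to 0.65 (adjusted p = 0.894).

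In WT epididymal fat HFD raised 4346 and lowered 3794 genes, among them most macrophage genes. Of the called genes 53.4% rose, but 48.2% with RLE size factors and 47.5% with DESeq2, so which direction prevails is not settled. Lipid-associated macrophage genes rose in 10 of 12 cases, also adjusted over the list alone, with Trem2 going from 4.67 ± 1.3 to 143 ± 18 CPM (4.94 ± 0.24) and Gpnmb at 6.01 ± 0.32 (adjusted p = 1.64e-18 preset and 0.00617 estimated). All 14 proliferation genes rose, also alone, with Ccna2 at 3.22 ± 0.14 (adjusted p = 6.64e-21 preset and 0.0102 estimated). General macrophage genes rose in 13 of 15 cases and fell in 2, also alone (adjusted p = 3.79e-10, and adjusted p = 0.232 with an estimated correlation). Inflammatory cytokines rose in 12 of 15, also alone, with Il1rn at 5.43 ± 0.36 (adjusted p = 0.000252, and adjusted p = 0.262 with an estimated correlation), and extracellular matrix genes in 22 of 25, 23 alone (adjusted p = 3.75e-11, and adjusted p = 0.232 with an estimated correlation). Lipolysis genes fell in 5 of 13 cases and rose in 1, also alone, with Adrb3 at -3.65 ± 0.25 and Lipe at -1.08 ± 0.16 (adjusted p = 0.0301, and adjusted p = 0.673 with an estimated correlation). Tph2 (8.30 ± 0.32), Xirp2 (8.13 ± 1.53), Serpinb1c (8.06 ± 0.65) and Gpr50 (7.73 ± 0.47) were among the largest rises, with the liver paralogs Mup19 (10.50 ± 1.46), Mup11 (9.57 ± 1.62) and Mup3 (8.44 ± 1.51). Without WT HFD libraries 4 and 5, which held 798.1 and 3261 CPM of Alb, and KO HFD library 8, these Mup genes lay at 6.41, 4.30 and 1.27, still called, and Xirp2 at 7.33, Cyp2e1 at -5.40 and Acsm3 at -5.60. Hmga1b (-5.50 ± 1.31), the complement factor D gene Cfd (-5.23 ± 0.29), Cyp2e1 (-4.59 ± 0.48), Acsm3 (-4.08 ± 0.51), Syt14 (-3.80 ± 0.26) and Tmem88b (-3.78 ± 0.27) were among the largest falls. Acvr1c fell from 364 ± 110 to 89.6 ± 29.2 CPM (-2.02 ± 0.26, adjusted p = 9.56e-08).

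In KO mice HFD raised 1661 and lowered 1287 subcutaneous genes, and raised 3719 and lowered 2098 epididymal ones; there 63.9% of the called genes rose, and 53.7% with DESeq2. Mest and Slc5a7 rose with HFD in the absence of Inhbe, Mest by 4.28 ± 0.36 in subcutaneous and 4.64 ± 0.23 in epididymal fat and Slc5a7 by 6.39 ± 0.66 and 7.51 ± 0.49. In WT mice these values were 5.24 ± 0.34, 2.07 ± 0.19, 5.39 ± 0.50 and 4.59 ± 0.35, so their levels do not follow Inhbe alone. The subcutaneous count was 6836 with limma-voom and 6463 when only the 2 groups were fitted. Cholesterol synthesis rose in 14 of 18 subcutaneous cases with 1 lower, 15 and 1 alone (adjusted p = 2.28e-13 preset and 0.0155 estimated), and thermogenic genes in 9 of 13 epididymal ones, also alone (adjusted p = 2.45e-07 preset and 0.00707 estimated).

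The effect of KO on HFD ran against the effect of HFD in WT. WT HFD libraries enter both comparisons, so they were split into 2 separate sets, 1 per comparison, over 35 draws. The correlation across genes was then -0.426 in subcutaneous (range -0.543 to -0.122) and -0.543 in epididymal fat (-0.693 to -0.2), against -0.001 and -0.004 in 20 simulations of unchanged groups. With all libraries it was -0.645 and -0.674, against -0.53 and -0.502 simulated, since shared libraries alone bring a negative value. The covariance of the fold changes was -0.285 and -0.424 against -0.0344 and -0.053 simulated, differences of -0.25 and -0.371.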

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

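Apart from the counts of called genes over regroupings of libraries, the tests of explanations below were chosen after the results were seen. In the regroupings, libraries were assigned to groups in 100 ways, the real one included, and the value given is how many ways gave as many called genes as the real one. For the AAV in subcutaneous fat it was 1 of 100 (highest other count 0), and in epididymal fat 2 of 100, where another grouping gave 2975 calls, so a structure of the samples other than the vector exists there. For KO on chow it was 7 of 100 in subcutaneous fat (highest other 186) and 1 of 100 in epididymal fat (highest other 67). In subcutaneous fat the count of 36 alone thus does not exclude chance, and a structure of the samples other than the genotype exists there. The smallest adjusted p there, Mest's 1.69e-07, was reached by 1 of 100 ways, the real one (lowest other 0.00154). This measure was chosen after the count was seen, and 100 ways can give no value below 1. It therefore does not exclude chance by itself. For the 27 calls of opposite sign with the AAV, 3 of 100 ways gave as many shared calls of either sign. The others gave at most 34 of the same and 2 of the opposite sign. A structure of the samples can thus yield as many shared calls, so this measure, chosen after the count was seen, does not exclude chance. For KO on HFD it was 1 of 100 in subcutaneous (highest other 1004) and 1 of 100 in epididymal fat (highest other 2615). For HFD in WT it was 1 of 100 (highest other 4303) and 1 of 100 (highest other 5130), and for HFD in KO 1 of 100 (highest other 1602) and 1 of 100 (highest other 5165). For the KO effect between diets it was 1 of 100 (highest other 0) and 1 of 100 (highest other 414). Between depots it was 1 of 100 for the AAV (highest other 27) and 1 of 100 for KO on HFD (highest other 1711). For KO on chow between depots 0 genes were called, so all 100 of 100 ways give as many and this tests nothing (highest other 72).

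Once 5 libraries holding liver transcripts were left out, Alb, the albumin gene, was called higher in KO than in WT libraries. In subcutaneous fat it was also lower with mInhbe. There it lay at 82.5 ± 12.3 CPM in KO and 24.8 ± 7.89 in WT on chow, and at 8.73 ± 2.74 with mInhbe and 26.3 ± 8.12 with GFP (-1.59 ± 0.21, adjusted p = 5.3e-05). In epididymal fat the AAV effect on Alb did not pass (-0.63 ± 0.23, adjusted p = 0.285). Liver tissue carried into the KO libraries could raise Alb, but would bring Apoa1 as well. The Apoa1 to Alb ratios of WT HFD epididymal libraries 4 and 5 were 0.0773 and 0.0898, lower value first. By the lower ratio the KO libraries would hold a median of 4.39 CPM of Apoa1, and the median ratio over the 30 KO libraries was 0. With all libraries Alb was called for KO on HFD only, higher in subcutaneous (1.95 ± 0.58, adjusted p = 0.0184) and lower in epididymal fat (-4.57 ± 1.29, adjusted p = 0.00589). Without the 5 KO experiment libraries that hold liver transcripts (WT HFD subcutaneous 6, KO HFD subcutaneous 2, WT HFD epididymal 4 and 5 and KO HFD epididymal 8) Alb was called higher in 4 of 4 KO comparisons (1.74 ± 0.29 and 3.02 ± 0.34 in subcutaneous fat on chow and HFD, 0.94 ± 0.16 and 4.12 ± 0.21 in epididymal fat). These libraries were marked by liver transcripts, Alb among them, and include the WT HFD libraries with the most Alb. Leaving them out thus itself favours a higher Alb in KO on HFD. On chow no library of the compared groups was left out. The chow fold changes were 1.745 with and 1.735 without the 5 libraries in subcutaneous fat, and 0.941 both ways in epididymal fat. Whether fat cells make more Alb where Inhbe is absent, or a small shared contaminant contributes, stays open.

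Macrophage and lipid-associated macrophage transcripts were lower in KO than in WT epididymal fat on HFD, with medians of -1.24 and -2.09. Liver tissue in WT HFD libraries 4 and 5 and KO HFD library 8 could distort the contrast, but without these 3 libraries 10 members of the lipid-associated macrophage list were still called lower (median -2.07). A larger share of fat cells would lower all other cell types alike, but the endothelial median stood 1.291 above the macrophage median, at 0.06. T cell genes stood at 0.23, Schwann cell genes at 0.35, preadipocyte and fibroblast genes at -0.34 and mast cell genes at -1.63. A larger share of fat cells alone would not give such uneven medians, but it could still contribute. The tables are consistent with fewer macrophages or with less transcript of these genes per macrophage, and bulk libraries cannot separate the possibilities.

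Some imprinted genes were called higher with mInhbe and lower in KO on chow: Mest in both depots, Klf14 in epididymal fat, and Peg3 and Zim1 in subcutaneous fat. Passenger DNA around the Inhbe locus could change genes near it in KO mice, but 0 of these 4 lie within 10 Mb of Inhbe. Their places were fixed whatever the counts, so this speaks only to direct effects on neighbours. Of the genes within 10 Mb, 0 of 107 in subcutaneous and 0 of 112 in epididymal fat were called for KO on chow. Elsewhere 36 of 14113 and 99 of 14930 were called, so few calls near Inhbe could be awaited either way. Whether imprinted genes move together as a class cannot be told: over 26 tested genes the adjusted camera p was 0.213 and 0.0957 with the AAV, 0.000106 and 6.3e-11 for KO on chow and 0.000976 and 0.22 for KO on HFD, where 11 fell and 4 rose in epididymal fat. With the AAV 4 rose and 6 fell in subcutaneous fat. Allele of origin is not seen in counts per gene, so loss or gain of imprinting stays untested.

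In groups of 7, 8 or 10 libraries, library totals and the CPM of 7 genes were tested for a single library far from the others. Over these 96 sets 23 ends stood out, nearly all of them the highest library of a set. For normally distributed values chance marks about 1 in 20 sets. CPM values need not be so distributed, so this rate may not hold here. Library totals in 1e+06 counts were 14.4 in GFP subcutaneous 2, 17.7 in KO chow subcutaneous 2 and 19.7 in WT HFD epididymal 3. Slc5a7 was at 6.7 CPM in GFP subcutaneous 7, 12.8 in WT chow subcutaneous 3 and 0.835 in KO chow subcutaneous 2. Lipe was at 3620 CPM in GFP subcutaneous 2, 2800 in mInhbe subcutaneous 4, 1990 in WT HFD subcutaneous 6 and 2200 in KO HFD epididymal 4. Pmepa1 was at 940 CPM in mInhbe subcutaneous 4 and 57.4 in KO chow epididymal 5. Trem2 was at 2.2 CPM in mInhbe subcutaneous 2, 12 in mInhbe epididymal 9, 2.77 in KO chow subcutaneous 5, 6.17 in KO HFD subcutaneous 3 and 182 in WT HFD epididymal 5. Mest was at 413 CPM in GFP epididymal 4. Adrb3 was at 673 CPM in GFP epididymal 7 and 67.2 in WT HFD subcutaneous 7. Acvr1c was at 462 CPM in GFP epididymal 7, 281 in mInhbe epididymal 10 and 488 in WT chow subcutaneous 1.

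Differences of log2 fold changes are given here for the 5 smallest adjusted p of each sign. The KO effect differed between diets for 304 genes in subcutaneous fat, with Cyp2e1 3.15, Cyp2f2 2.52, Elovl7 2.52, Nap1l5 2.22, Ppp1r3b 1.32, Hp -2.19, Ubd -2.33, Fam83d -3.21, Ctsl -1.25 and Lrg1 -1.85. It differed for 2487 genes in epididymal fat, with Disp2 2.48, Ces1d 2.17, Car1 2.55, Mest 2.57, Aldh5a1 1.24, Cd9 -1.49, Ctsk -1.81, C2cd2 -1.05, Stxbp2 -1.06 and Gla -1.40. The AAV effect differed between depots for 2081 genes, with Ctnnbip1 0.76, Tmed4 0.49, Mpi 0.56, Pecr 0.68, Prdx6 0.80, Dennd2d -1.32, Tlcd4 -2.49, Ptprc -1.41, Bhlhb9 -0.90 and Osbpl9 -0.56. Here Tmed4, Mpi, Pecr, Prdx6 and Osbpl9 came from a tie at an adjusted p of 0.013 that other genes shared. The KO effect on HFD differed between depots for 2264 genes, with Mest 3.19, Retn 2.05, Krt79 2.58, Rhbdl1 1.74, Vnn3 1.64, Nfya -0.99, Skap2 -0.92, Pacc1 -1.33, Dlg3 -1.73 and Taok3 -1.33.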

How the results depend on the processing

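Of 127 values recomputed under other settings 94 stayed within 1.5 times and 33 moved or changed sign; of 5347 named-gene values 5026 stayed the same, 316 lost their call, 2 gained one and 3 changed sign. The cause was not tested.

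DESeq2 called 314 genes for the AAV in epididymal fat, 119 and 182 for KO on chow in subcutaneous and epididymal fat, 569 for the KO effect between diets in subcutaneous fat and 19 for KO on chow between depots. limma-voom called 5786 (AAV, subcutaneous), 338 (AAV, epididymal), 272 and 257 (KO on chow, subcutaneous and epididymal), 5552 (KO on HFD, subcutaneous), 6836 (HFD in KO, subcutaneous), and 2500 and 3945 (KO effect between diets, subcutaneous and epididymal). A tissue score as a covariate gave 524 and 262 for the AAV in subcutaneous and epididymal fat and 71 for KO on chow, subcutaneous. Only the 2 groups compared gave 23 and 162 for KO on chow in subcutaneous and epididymal fat, and 3867 and 6463 for HFD in WT and KO subcutaneous fat.

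With the replicate number as a replicate block 76 genes were called for the AAV in epididymal fat, 23 for KO on chow in subcutaneous fat and 4 for the AAV between depots. In no pair of groups did every same-number pair correlate above 0.1, and at most 3 libraries matched their own number best. This rule cannot exclude a weak or partial pairing. Between GFP and mInhbe epididymal libraries the median was 0.226 (range -0.447 to 0.687), with 6 of 10 pairs above 0.1. Whether a number marks the same mouse in both depots is not stated, and the main fits treated all libraries as independent.

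Chosen after seeing the data, 188 genes were called for KO on chow in epididymal fat without KO HFD library 4. For KO on chow in subcutaneous fat 64 were called without WT HFD library 6 and KO HFD library 2, and 102 without WT chow library 1 and WT HFD libraries 1, 2 and 4. Without GFP subcutaneous library 2 and GFP epididymal libraries 7 and 8, 877 were called for the AAV between depots.

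With an estimated correlation 16 gene list tests were called in place of 175. The correlation of AAV with KO effects was -0.002 in subcutaneous fat with KO on HFD, and in epididymal fat -0.219 with KO on HFD and -0.031 over genes with log2 CPM above 3. The correlation of KO on HFD with the HFD effect over genes called for HFD was -0.587 in subcutaneous and -0.688 in epididymal fat. Signs changed for Mup18 with HFD in WT subcutaneous fat (0.654, limma-voom), Acvr1c in KO chow epididymal fat (-0.016, limma-voom) and Serpina1b in KO HFD epididymal fat (0.294, without WT HFD libraries 4 and 5 and KO HFD library 8).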

Other observations

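HFD changed clock, mesothelium and acute stress transcripts of WT fat that no comparison above was set up around. Circadian clock genes, which time daily metabolism, fell in 10 of 15 cases in epididymal fat, and adjusted over the list alone 10 fell and 2 rose, with Per3 at -1.39 ± 0.15 and Tef at -0.98 ± 0.12 (adjusted p = 0.0109, and adjusted p = 0.232 with an estimated correlation). The hour of tissue collection is not known here. Mesothelium genes, which line the fat pad, fell in 6 of 7 cases and in 7 adjusted over the list alone, with Lrrn4 at -2.30 ± 0.34 (adjusted p = 0.00168, and adjusted p = 0.444 with an estimated correlation). Immediate early genes, which mark acute stress, rose in 5 of 13 cases, also alone, with Atf3 at 4.61 ± 0.21 and Fos at 2.86 ± 0.28 (adjusted p = 0.0131, and adjusted p = 0.598 with an estimated correlation). In KO epididymal fat on HFD 6 of the 13 fell against WT, also alone (adjusted p = 0.00775, and adjusted p = 0.564 with an estimated correlation). Unfolded protein response genes rose with HFD in 7 of 12 cases and 1 fell, also alone, with Sdf2l1 at 1.49 ± 0.20 (list adjusted p = 0.126). Red blood cell genes fell in 4 of 7 cases, also alone, with Hbb-bt at -0.89 ± 0.25 (list adjusted p = 0.26).

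Insulin signalling genes fell with HFD in WT epididymal fat in 10 of 16 cases and rose in 4, also adjusted over the list alone, with Irs1 at -1.41 ± 0.16 and Insr at -1.05 ± 0.13 (adjusted p = 0.0272, and adjusted p = 0.337 with an estimated correlation). In KO on HFD 8 of the 16 rose and 4 fell against WT, also alone (adjusted p = 0.027, and adjusted p = 0.337 with an estimated correlation). Elovl3, a fatty acid elongase gene of brown fat and skin, rose by 7.47 ± 0.81 and the proton channel gene Otop1 by 5.59 ± 0.34 with HFD in WT epididymal fat, and thermogenic genes rose there in 9 of 13 cases with 1 lower, also alone (adjusted p = 0.0101, and adjusted p = 0.232 with an estimated correlation). Among adipokines Retn fell (-2.46 ± 0.18) and Lep rose (1.64 ± 0.23). Preadipocyte and fibroblast genes rose with the AAV in subcutaneous fat in 5 of 11 cases, and in 6 adjusted over the list alone, and the list missed camera's threshold (adjusted p = 0.0772). Mammary and skin epithelium genes, which a subcutaneous pad can carry along, had 1 of 8 called there, also alone (list adjusted p = 0.293).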
